A study of Homo sapiens with 8 samples.

How the data were processed

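RNA from 8 samples of human colon cancer cells had been hybridised to Affymetrix arrays with 54675 probe sets, 1 array per sample. The labels put the samples in 4 groups of 2: HT29 parental cells and HT29 cells grown as spheres, and SW480 stable lines made with an empty vector or expressing Snail. HT29 and SW480 are established lines derived from human colorectal adenocarcinomas. Parental HT29 cells and both SW480 lines were grown in medium with 10% fetal bovine serum, and the spheres in DMEM-F12 with N2 supplement, 10 ng/ml bFGF and 10 ng/ml EGF, per the labels' protocols. Replicate numbers were taken from the labels, which do not say that the arrays of a group came from separate cultures. P-values therefore measure the spread between these arrays, which may be technical.

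The deposited values are log2 expression values, 1 per probe set and array, that the authors made with RMA, per the submitters' processing notes. RMA corrects background, normalises the arrays to a common distribution and summarises the probes of each probe set; its version, the probe definitions and the arrays processed together are not given in the sources used here. The values reached 14.4 on the log2 scale and no array median exceeded 5.61, and no further scaling was applied. No measure of detection against background was used here, so low values carry no statement on whether a transcript was present.

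Probe sets were named through GEO's annotation of the platform. Of the 54675 probe sets, 62 were Affymetrix controls, 41091 named 1 gene, 1801 named several genes and 11721 were not named by the annotation used. Entrez identifiers of 41037 probe sets matched the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols; it was used for names only. Older symbols in the gene lists were brought to current ones through the same table. Each of 19775 genes was represented by its brightest probe set, the one with the highest mean over the 8 arrays among those naming 1 gene, and probe sets naming several genes or none stayed out of the gene table.

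Gene tests used limma 3.58.1 in R 4.3.3. A mean per group was fitted to all 8 arrays, so that the 4 groups shared 1 estimate of the spread per gene with 4 residual degrees of freedom, to which the empirical Bayes step added 6.10 prior degrees of freedom. The contrasts were HT29 sphere minus parental, SW480 Snail minus vector, and the difference between these. Tests were two-sided, p-values were adjusted over all 19775 genes by Benjamini-Hochberg, and the threshold was an adjusted p under 0.05. A permutation test of 2 arrays against 2 cannot give a two-sided exact p under 0.333, so no such test was used for single genes. Throughout, group means are given ± SD over 2 arrays, and log2 fold changes ± SE from limma. Overlaps of called genes were set against independent lists of the same sizes. Because both contrasts use 1 estimate of each gene's spread, they were also set against lists matched in 10 bins of that spread by 10 bins of mean level, with the Cochran-Mantel-Haenszel test, two-sided and adjusted over the 4 overlaps, an alternative chosen after the data were seen. Fold changes were correlated across genes as a description, since genes are not independent replicates. The overlap tests count genes as independent too, so their p-values are descriptive.

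The 21 gene lists held 441 entries, of which 412 were measured: EMT transcription factors, epithelial junction and identity, mesenchymal and matrix, intestinal and colon cancer stem cell, pluripotency, Wnt targets, Notch signalling, NF-kB cytokines, interferon response, drug efflux and resistance, NRF2 and oxidative stress, hypoxia and glycolysis, cholesterol synthesis and uptake, fatty acid synthesis, cell cycle, enterocyte differentiation, goblet and secretory, amino acid and ER stress response, EGF and FGF immediate response, metallothioneins, and other cell types. Each list was set against all other genes with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 21 lists. Camera with an estimated correlation, which then uses the 4 residual degrees of freedom, and limma's fry were alternatives. Fry tests whether the members move one way on balance and makes no comparison with other genes.

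The groups, tests, gene lists, processing alternatives and the rule for naming genes were fixed before the data were examined. The rule named SNAI1 first, as a check of the labels. It then took, per comparison, the 6 largest rises and the 6 largest falls among genes past the threshold whose arrays did not overlap between the groups. Up to 2 members of each list with the lowest adjusted p followed, and, for a list with none past the threshold, the member with the lowest adjusted p as a value only. CXCL8, CDH1, VIM, CD44, PROM1 and LGR5 were named in every case. Of genes past the threshold in both comparisons it took the 5 largest in each shared direction, and for the difference between the comparisons the 4 largest each way. Other genes printed are members of the lists or are said to have been chosen after their values were seen.

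The fit was tested on simulated data with the arrays' own means and spreads, in which 100 genes were changed 2-fold and 100 changed 1.5-fold among 19775. For HT29, 58% of the 2-fold and 10% of the 1.5-fold changes were recovered, and 0 of 68 called genes had been left unchanged. For SW480, 61% and 5% were recovered, and 1 of 67 called genes had been left unchanged. The simulated noise was independent between genes and equal in all groups, and far fewer genes were changed than were called on the real arrays. These rates therefore do not carry over to the real arrays. The number of arrays limits the precision, with a median SE of 0.148 log2 per gene.

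The alternatives tried were the mean of a gene's probe sets, every probe set on its own, leaving out the dimmest 40% of genes, quantile normalisation of the deposited values, centring each array on its median, each cell line fitted alone, an intensity trend, array weights, the replicate number as a block, an added requirement of a 2-fold change, and leaving out each array in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.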

Results

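Gene expression was measured on 8 arrays, 2 for each of 4 groups: HT29 parental cells, HT29 spheres, SW480 cells carrying an empty vector, and SW480 cells labelled as expressing Snail. The lower quartiles of the arrays lay between 4.28 and 4.38 log2, and no median exceeded 5.61. Over 19775 genes, partner arrays correlated at 0.991 in HT29 parental cells, 0.995 in spheres, 0.995 in vector cells and 0.995 in the arrays labelled Snail. The HT29 parental pair was the least alike of the 4 pairs, with 200 genes at least 2-fold apart, against 13, 19 and 10 in the other pairs.

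HT29 spheres differed from parental HT29 cells in proliferation, sterol and low-oxygen genes: all 30 measured cell cycle genes fell, while 14 of 15 cholesterol synthesis and uptake genes and 19 of 22 hypoxia and glycolysis genes rose. Oxidative stress, NF-kB cytokine and interferon response genes were higher as groups by camera at its preset correlation, but no list passed with an estimated correlation (lowest adjusted p 0.082). The largest rises were in PI3, the elastase inhibitor elafin, at 6.72 ± 0.24 log2 (limma adjusted p = 1.0e-07), and in SPRR1B, a cornified envelope protein, at 6.42 ± 0.17. FGF19, a secreted growth factor of the FGF family, fell by 5.75 ± 0.15 log2, from 11.18 ± 0.02 to 5.43 ± 0.28. SNAI1, which encodes the repressor Snail, was 2.09-fold higher in spheres.

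The comparison asks which genes change when HT29 cells, which otherwise grow attached in serum, are grown as spheres in serum-free medium with growth factors, a culture often used to enrich stem-like tumour cells. At an adjusted p under 0.05, limma called 6200 of 19775 genes (31.4%), of which 2448 were higher and 3752 lower in spheres. A change of at least 2-fold was also met by 624 higher and 1400 lower genes. With each line fitted alone 5101 genes passed in spheres, and with array weights 5295. Every sphere array had the serum-free medium and no parental array did, so medium and sphere form were not separated. The BioC spike-in, a bacterial transcript added at hybridisation, read 8.82 ± 0.08 log2 on the parental arrays and 10.47 ± 0.00 on the sphere arrays, while the other control spike-ins differed by 0.32 log2 or less between these groups.

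SNAI1, read by 1 probe set, stood at 6.01 ± 0.20 in parental cells and 7.07 ± 0.20 in spheres, a rise of 1.07 ± 0.15 log2 (limma adjusted p = 0.00032). After PI3 and SPRR1B, the largest rises were in HSPA6, an inducible heat shock protein (5.37 ± 0.13), NWD2 (5.29 ± 0.14), and CEACAM7 and CEACAM5, surface glycoproteins of the carcinoembryonic antigen family, at 5.07 ± 0.19 and 4.75 ± 0.18. A dimmer second probe set of CEACAM5 changed by only 0.09. The parental values of SPRR1B (4.86), HSPA6 (5.11) and NWD2 (3.48) lay below every array's median, where detection was not measured, so the sizes and ranks of these rises rest on values that may be background. After FGF19, the largest falls were in GABRP, a GABA receptor subunit (-5.41 ± 0.26), RARRES1 (-4.61 ± 0.15), DTL, which acts in DNA replication control (-4.15 ± 0.20), ADRA2A, an adrenergic receptor (-4.01 ± 0.32), and MYB, a transcription factor of progenitor cells (-3.76 ± 0.19). The same limit holds for these falls, since the sphere values of FGF19 (5.43), GABRP (3.82), RARRES1 (5.03), DTL (5.43) and ADRA2A (4.92) lay below every array's median. CXCL8, which encodes interleukin 8, rose from 6.20 ± 0.76 to 9.82 ± 0.02, or 12.3-fold (adjusted p = 7.9e-06).

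**Figure D1:**
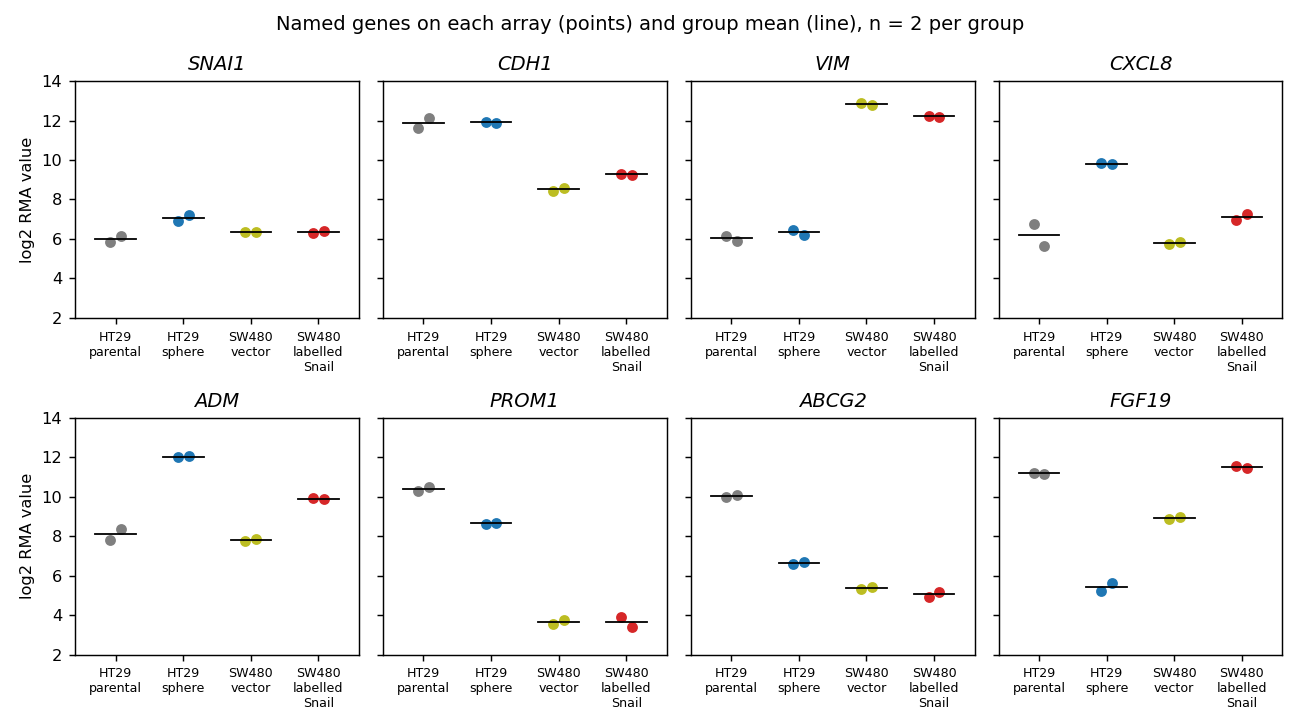
Log2 RMA values of 8 named genes on each array (points) with the mean of each group of 2 (lines). SNAI1 is higher in HT29 spheres (7.07) than in parental cells (6.01) and equal in the SW480 groups (6.35 in each).

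Genes of cell division fell throughout. All 30 measured cell cycle members fell (30 adjusted over the list alone), with a list median of -1.64 log2 (camera adjusted p = 2.2e-20; adjusted p = 0.24 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, fell by 2.24 ± 0.13, and TYMS, the thymidylate synthase targeted by fluorouracil, fell by 2.63 ± 0.17. In the hypoxia and glycolysis list 19 of 22 measured members rose, 0 fell and 3 did not pass (20 rose adjusted over the list alone), with a median of 1.44 log2 (camera adjusted p = 5.3e-15; adjusted p = 0.082 with an estimated correlation). ADM, the vasodilator peptide adrenomedullin, rose 15.2-fold and P4HA1, a collagen prolyl hydroxylase, 4.83-fold.

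Among the 15 measured cholesterol synthesis and uptake genes, 14 rose and 1 did not pass (14 rose adjusted over the list alone), with a median of 1.22 log2 (camera adjusted p = 2.5e-08; adjusted p = 0.24 with an estimated correlation). HMGCS1, which makes the precursor of mevalonate, rose by 2.62 ± 0.21 and SC5D, a late sterol desaturase, by 1.72 ± 0.16. The fatty acid synthesis list was mixed: of 9 measured members 4 rose, 2 fell and 3 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.53). FASN, the fatty acid synthase, rose by 1.03 ± 0.19 and ELOVL6, a fatty acid elongase, fell by 1.16 ± 0.16. NRF2 and oxidative stress genes rose in 10 of 17 cases with 0 falls and 7 not past (11 rose adjusted over the list alone), at a median of 0.69 log2 (camera adjusted p = 1.2e-07; adjusted p = 0.097 with an estimated correlation). HMOX1, the heme oxygenase, rose 8.77-fold and GCLM, a subunit of the enzyme that limits glutathione synthesis, 5.14-fold. Of 7 measured metallothioneins, 4 rose and 3 did not pass (5 rose adjusted over the list alone; camera adjusted p = 0.032; adjusted p = 0.49 with an estimated correlation), MT1X by 0.95 ± 0.19 and MT1E by 0.99 ± 0.21. The metallothionein call was lost without parental array 1 or without sphere array 2 (camera adjusted p up to 0.085).

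NF-kB cytokine genes rose in 13 of 22 cases, with 2 falls and 7 not past, the same counts adjusted over the list alone, at a median of 0.82 log2 (camera adjusted p = 1.6e-05; adjusted p = 0.082 with an estimated correlation). CCL20, a chemokine, rose by 3.18 ± 0.24, while TNFAIP2 fell by 2.16 ± 0.14. Interferon response genes rose in 14 of 24 cases, with 2 falls and 8 not past (15 rises and 4 falls adjusted over the list alone), at a median of 0.69 log2 (camera adjusted p = 0.00011; adjusted p = 0.13 with an estimated correlation). IFI6 rose by 2.07 ± 0.13 and MX1, an antiviral GTPase, by 1.86 ± 0.12.

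The epithelial junction and identity list had 15 rises, 4 falls and 15 members not past among 34 (15 rises and 6 falls adjusted over the list alone), at a median of 0.30 log2 (camera adjusted p = 0.011; adjusted p = 0.24 with an estimated correlation). OCLN, a tight junction protein, rose by 1.28 ± 0.12, and ESRP1, an epithelial splicing regulator, fell by 1.29 ± 0.14. CDH1, E-cadherin, stood at 11.89 ± 0.37 and 11.91 ± 0.04 (adjusted p = 0.95). The mesenchymal and matrix list had 6 rises, 2 falls and 21 members not past among 29, the same counts adjusted over the list alone (camera adjusted p = 0.13). CCN1, a matrix-associated signalling protein, rose by 1.72 ± 0.13 and TGFBI, a matrix adhesion protein, fell by 1.78 ± 0.15. VIM, vimentin, was 6.03 ± 0.17 and 6.34 ± 0.18 (adjusted p = 0.12). Of 12 EMT transcription factors, SNAI1 and FOXC2 rose, TCF3 and SNAI3 fell and 8 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.59). FOXC2 and SNAI3 were named after their values were seen. The 14 probe sets of TCF3 disagreed: the one used fell by 0.62 ± 0.13, and their mean gave 0.07 (adjusted p = 0.69).

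Stem cell and pluripotency genes moved both ways. In the intestinal and colon cancer stem cell list 2 of 17 members rose, 6 fell and 9 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.30). PROM1, the surface protein CD133, fell by 1.74 ± 0.17 (adjusted p = 3.9e-05), ALCAM, an adhesion molecule, by 1.53 ± 0.15, and LGR5, a receptor of crypt stem cells, by 1.23 ± 0.21 (adjusted p = 0.0012), or -4.35 with a dimmer probe set. CD44, a hyaluronan receptor, was 11.52 ± 0.35 and 11.12 ± 0.15 with the probe set used (adjusted p = 0.095), but 4 of its 13 probe sets rose, and changes ran from -0.41 to 1.12. Among 11 pluripotency genes, KLF4 (1.21 ± 0.13) and MYC (1.20 ± 0.15) rose, SALL4, chosen after its value was seen, fell by 0.77, and 8 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.33). Of 16 Wnt targets 5 rose, 2 fell and 9 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.13); AXIN2, a feedback inhibitor of the pathway, rose by 2.06 ± 0.12 and DKK1, a secreted inhibitor, by 2.06 ± 0.22. In the Notch signalling list HES4 (1.74 ± 0.14), the ligand JAG1 (1.74 ± 0.27) and HES1, named after its value was seen, rose, while 10 of 13 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.37).

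Differentiation markers rose in part. Of 28 enterocyte differentiation genes 9 rose, 2 fell and 17 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.0067; adjusted p = 0.13 with an estimated correlation); CEACAM5 and CEACAM7 led the list. Of 21 goblet and secretory genes 5 rose, 0 fell and 16 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.20 with an estimated correlation). TFF1 and TFF3, trefoil peptides of mucus, rose 9.48-fold and 5.69-fold. The goblet call was lost without the dimmest 40% of genes, after quantile normalisation, and without parental array 1 or sphere array 2, with a camera adjusted p up to 0.086.

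In the drug efflux and resistance list 4 of 23 members rose, 8 fell and 11 did not pass (5 rises and 9 falls adjusted over the list alone; camera adjusted p = 0.19). ABCG2, a drug efflux pump, fell by 3.39 ± 0.14, from 10.04 ± 0.06 to 6.64 ± 0.10 (adjusted p = 2.3e-07), and ALDH1A3, an aldehyde dehydrogenase, by 3.43 ± 0.16. Of 20 amino acid and ER stress response genes 6 rose, 8 fell and 6 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.53). PHGDH, the first enzyme of serine synthesis, fell by 2.36 ± 0.17, and DNAJB9, an ER chaperone partner, rose by 1.73 ± 0.14. In the EGF and FGF immediate response list 5 of 22 members rose, 6 fell and 11 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.53). FOSL1, an AP-1 subunit, rose by 2.30 ± 0.20 and ETV5, a transcription factor downstream of FGF signalling, fell by 2.32 ± 0.16. Of 20 markers of other cell types LUM, PECAM1 and CD3E rose and 17 did not pass (2 rises adjusted over the list alone; camera adjusted p = 0.051). LUM, a matrix proteoglycan, rose by 3.78 ± 0.15 with the probe set used and by 0.51 with a dimmer one. PECAM1 rose by 0.57 ± 0.16, and the mean of its probe sets gave -0.09 (adjusted p = 0.58).

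Thus 10 of 21 lists passed in spheres, 9 upward and 1 downward; with an estimated correlation 0 passed (lowest adjusted p 0.082), and fry called 15.

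**Figure D2:**
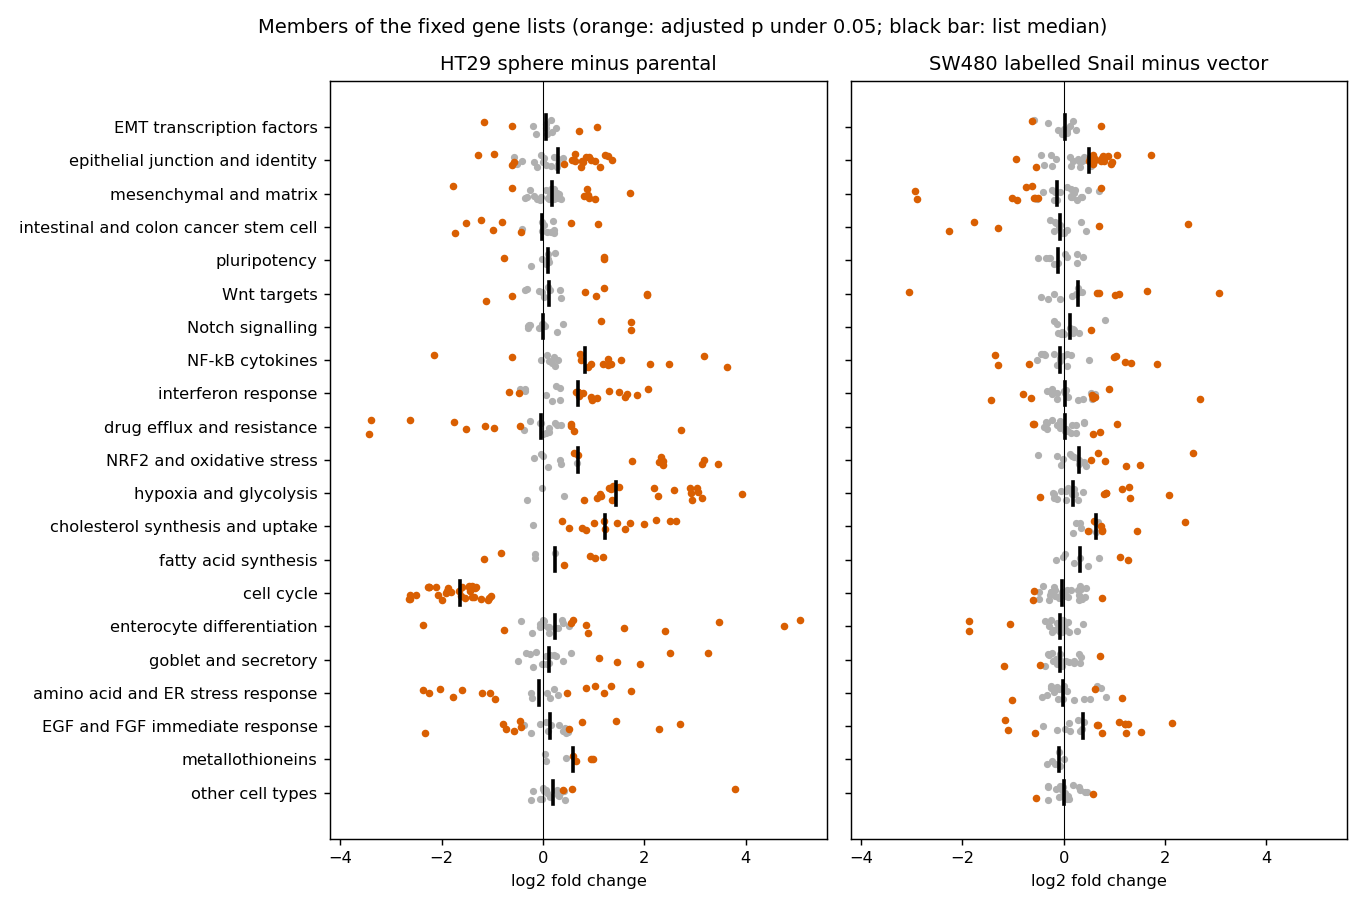
Log2 fold change of each measured member of the 21 gene lists (points), in HT29 spheres minus parental cells and in SW480 arrays labelled Snail minus vector. Orange points passed an adjusted p of 0.05 and black bars are list medians; the cell cycle median is -1.64 in the first panel and -0.02 in the second.

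In SW480 cells the arrays labelled Snail showed no rise of SNAI1 itself, and epithelial junction genes were higher rather than lower. SNAI1 read 6.35 ± 0.01 in vector cells and 6.35 ± 0.04 in the arrays labelled Snail (0.00 ± 0.15 log2, limma adjusted p = 0.99). Of 34 epithelial junction and identity genes 15 rose and 2 fell, but leaving out any 1 SW480 array left 5 to 8 rises. CDH1 was 1.69-fold higher, a call lost on leaving out any of 3 SW480 arrays, though its change stayed at 0.67 to 0.79 log2 there. SPARC and TNC, matrix proteins of mesenchymal cells, fell by 2.92 ± 0.13 and 2.89 ± 0.26. Cholesterol synthesis, NRF2, Wnt target and immediate response genes were higher as groups by camera at its preset correlation, but no list passed with an estimated correlation (lowest adjusted p 0.33).

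The comparison asks what a stable Snail line changes against its vector control. The direction of every change here rests on the label, which the SNAI1 values do not bear out: 1 probe set read SNAI1, the positions of its probes are not given in the sources used here, and a construct without the probed stretch would not register, so it checks only the transcript that it reads. At an adjusted p under 0.05, limma called 3213 genes (16.2%), 1762 higher and 1451 lower in the arrays labelled Snail. A change of at least 2-fold was also met by 379 higher and 277 lower genes. Leaving out 1 SW480 array lowered the count to 1472 (vector array 1), 1602 (vector array 2), 1527 (Snail array 1) or 1447 (Snail array 2). The count of 3213 also depended on the spread shared by the 4 groups, of which the HT29 parental pair was the least alike. With each line fitted alone 4004 genes passed, and with array weights 4649. Control probe sets for 18S and 28S ribosomal RNA, which lacks a poly(A) tail, were 1.40 and 0.94 log2 higher in the arrays labelled Snail. All 4 control spike-ins read lower there without overlap (BioC -0.52, BioB -0.33, BioD -0.44 and Cre -0.25 log2).

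The largest rises were in PRR9, a proline-rich protein (3.43 ± 0.19, adjusted p = 1.1e-05), KANK4 (3.23 ± 0.18), ADGRG2, an adhesion receptor (3.10 ± 0.16), DKK4, a secreted Wnt inhibitor (3.07 ± 0.13), IFI27, an interferon-induced gene (2.68 ± 0.17), and APOBEC3G, a cytidine deaminase (2.57 ± 0.20). A dimmer probe set of APOBEC3G gave -0.06, and the vector values of PRR9 (4.83), KANK4 (4.90) and ADGRG2 (4.47) lay below every array's median. NT5E, the surface nucleotidase CD73, fell by 3.89 ± 0.15, or 14.8-fold (adjusted p = 3.2e-06). The other large falls were in LINC00973 (-3.75 ± 0.40), TMEM200A (-3.69 ± 0.26), PDE8B, a cyclic AMP phosphodiesterase (-3.41 ± 0.16), PRKAR2B, a regulatory subunit of protein kinase A (-3.31 ± 0.20), and SLC26A4, an anion exchanger (-3.21 ± 0.19). The means over 8 arrays, those of HT29 included, of TMEM200A (4.68), PRKAR2B (4.78), SLC26A4 (4.69) and PDE8B (5.27) lay below every array's median. The sizes and ranks of these falls may thus rest on background values. CXCL8 rose from 5.80 ± 0.07 to 7.12 ± 0.23, or by 1.32 ± 0.28 (adjusted p = 0.0096). The call was lost without vector array 1 (change of 1.28) or Snail array 2 (1.16).

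Epithelial junction and identity genes rose in 15 of 34 cases, with 2 falls and 17 not past (20 rises and 4 falls adjusted over the list alone), at a median of 0.50 log2 (camera adjusted p = 2.9e-05; adjusted p = 0.33 with an estimated correlation). ESRP1 rose by 1.73 ± 0.14 and CDS1, a phospholipid synthesis enzyme, by 0.94 ± 0.12. CDH1 rose from 8.51 ± 0.12 to 9.27 ± 0.04, or by 0.76 log2 (adjusted p = 0.013), and the mean of its probe sets gave 0.52 (adjusted p = 0.081). Leaving out vector array 1, Snail array 1 or Snail array 2 gave 0.67, 0.73 or 0.79 log2, with the call lost in each. Such fits leave 1 array in a group and are less precise. A lost call or fewer members past the threshold there does not by itself show that an effect moved. The number of rising members was 8 without vector array 1, 7 without vector array 2, 5 without Snail array 1 and 6 without Snail array 2.

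Mesenchymal and matrix genes fell in 9 of 29 cases, with 1 rise, of ACTA2 (0.73, named after its value was seen), and 19 not past (4 rises and 10 falls adjusted over the list alone; camera adjusted p = 0.10). The camera call depended on the genes entered: adjusted p = 0.018 with the mean of each gene's probe sets and 0.037 without the dimmest 40% of genes. With an estimated correlation and all genes, camera gave adjusted p = 0.38. VIM fell by 0.62 ± 0.14, from 12.84 ± 0.05 to 12.22 ± 0.02 (adjusted p = 0.013). The call was lost, with little change in size, without vector array 1 (-0.59), vector array 2 (-0.66), Snail array 1 (-0.64) or Snail array 2 (-0.61). Falling members numbered 4, 3, 3 and 5 in those fits. Of 12 EMT transcription factors PRRX1 rose (0.74 ± 0.15), TCF3 fell (-0.63 ± 0.13) and 10 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.86); the list's median was 0.03, its mean -0.02 and its camera direction down. With the mean of each gene's probe sets neither passed: TCF3 was at -0.11 (adjusted p = 0.62) and PRRX1 at 0.56 (adjusted p = 0.062).

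Cholesterol synthesis and uptake genes rose in 7 of 15 cases with 0 falls and 8 not past (13 rises adjusted over the list alone), at a median of 0.63 log2 (camera adjusted p = 5.4e-06; adjusted p = 0.38 with an estimated correlation). STARD4, a sterol carrier, rose by 1.44 ± 0.22 and SREBF2, the transcription factor that drives the pathway, by 0.75 ± 0.13. Without vector array 2 or without Snail array 2, 3 members rose. In the fatty acid synthesis list SREBF1 (1.28 ± 0.14) and SCD (1.10 ± 0.22) rose and 7 of 9 did not pass (5 rises adjusted over the list alone; camera adjusted p = 0.036; adjusted p = 0.51 with an estimated correlation). That call was lost under 5 of 16 alternatives, with vector array 2 or Snail array 2 left out among them (camera adjusted p up to 0.18). NRF2 and oxidative stress genes rose in 6 of 17 cases with 0 falls and 11 not past (7 rises adjusted over the list alone; camera adjusted p = 0.0011; adjusted p = 0.33 with an estimated correlation), among them SLC7A11, the cystine importer (2.56 ± 0.29), and ME1, the malic enzyme (2.83-fold). In the hypoxia and glycolysis list 7 of 22 rose, 1 (HK2, named after its value was seen) fell and 14 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.38 with an estimated correlation). ADM rose 4.25-fold and ANKRD37 2.49-fold. Without the dimmest 40% of genes the hypoxia and Wnt calls were each lost (camera adjusted p = 0.054).

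Wnt targets rose in 6 of 16 cases, DKK1 fell by 3.05 ± 0.22 and 9 did not pass (7 rises and 1 fall adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.33 with an estimated correlation). The largest rise in that list was that of DKK4. Without Snail array 2, 3 members rose. EGF and FGF immediate response genes rose in 10 of 22 cases, with 3 falls and 9 not past (11 rises and 3 falls adjusted over the list alone; camera adjusted p = 0.0022; adjusted p = 0.38 with an estimated correlation). EGR1, an early growth response factor, rose by 2.14 ± 0.25 and IER2 by 1.09 ± 0.15. Of 17 stem cell genes 2 rose, 3 fell and 12 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.50): ASCL2, a regulator of intestinal stem cells, rose by 2.46 ± 0.16 and CD24, a surface glycoprotein, fell by 2.27 ± 0.13. CD44 was 9.74 ± 0.06 and 9.59 ± 0.08 with the probe set used (adjusted p = 0.62), while 1 of its 13 probe sets rose, by 1.40. PROM1 was 3.65 ± 0.13 and 3.65 ± 0.35 (adjusted p = 1.0), and LGR5 4.76 ± 0.23 and 5.10 ± 0.06 (adjusted p = 0.31).

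The remaining lists did not pass. NF-kB cytokines had 5 rises, 3 falls and 14 members not past among 22 (5 rises and 7 falls adjusted over the list alone; camera adjusted p = 0.74), with LIF at 1.03 ± 0.14 and RELB at -1.29 ± 0.18; the list's median was -0.07, its mean 0.06 and its camera direction down. Interferon response had 5 rises, 3 falls and 16 not past among 24 (7 rises and 3 falls adjusted over the list alone; camera adjusted p = 0.73), but 2 rises without any 1 of the 4 SW480 arrays and 8 without either HT29 parental array. Of its members, IFI27 rose and BST2, which tethers virus particles, fell by 1.43 ± 0.14. Drug efflux and resistance had 3 rises, 2 falls and 18 not past among 23 (4 rises and 2 falls adjusted over the list alone; camera adjusted p = 0.90), with ALDH1A3 at 1.05 ± 0.16 and ABCC5 at -0.58 ± 0.14. In the cell cycle list 1 of 30 rose, 2 fell and 27 did not pass (1 rise and 0 falls adjusted over the list alone; camera adjusted p = 0.86), with MCM6 at 0.76 ± 0.16, RRM2 at -0.58 ± 0.15 and TYMS at -0.61. Enterocyte differentiation had 3 falls, of CA2 (-1.86 ± 0.13), MUC13 (-1.86 ± 0.21) and VIL1, and 25 of 28 not past, the same counts adjusted over the list alone (camera adjusted p = 0.13). Goblet and secretory genes had 1 rise, of DEFA5 (0.72 ± 0.18), 2 falls, of CHGB (-1.18 ± 0.19) and LYZ, and 18 of 21 not past, the same counts adjusted over the list alone (camera adjusted p = 0.71). VIL1 and LYZ were named after their values were seen. Amino acid and ER stress response had rises of ATF3 (1.15 ± 0.16) and ATF4, a fall of HSPA5 (-1.02 ± 0.14) and 17 of 20 not past, the same counts adjusted over the list alone (camera adjusted p = 0.73; median -0.004, mean 0.12, camera direction up). ATF4 was named after its value was seen. Notch signalling had 1 rise, of NOTCH2 (0.54 ± 0.14), among 13, the same count adjusted over the list alone (camera adjusted p = 0.54). Other cell types had PECAM1 at -0.55 ± 0.16 and MAP2 at 0.58 ± 0.16 among 20, with 0 past when adjusted over the list alone (camera adjusted p = 0.86). In the pluripotency list 0 of 11 passed (camera adjusted p = 0.73), LIN28A having the lowest adjusted p (-0.35 ± 0.12, adjusted p = 0.080), and 0 of 7 metallothioneins passed (camera adjusted p = 0.54), MT1E having the lowest (-0.32 ± 0.21, adjusted p = 0.36); both counts were 0 when adjusted over the list alone.

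Thus 7 of 21 lists passed, all upward; with an estimated correlation 0 passed (lowest adjusted p 0.33), and fry called 9.

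The design also asks whether sphere culture and the Snail line changed the same genes. Both comparisons raised INSIG1, a brake on sterol synthesis (2.23 ± 0.42 in spheres and 2.40 ± 0.42 in the arrays labelled Snail), ADM (3.92 ± 0.17 and 2.09 ± 0.17), RARRES2, the chemoattractant chemerin (2.77 ± 0.25 and 1.95 ± 0.25), CXCL2, a chemokine (2.48 ± 0.27 and 1.84 ± 0.27, while its 2 dimmer probe sets passed in neither), and H1-2, a linker histone (2.39 ± 0.31 and 1.83 ± 0.31). Both lowered LCN2, an iron-carrier-binding lipocalin (-2.35 ± 0.16 and -2.25 ± 0.16), GDA, guanine deaminase (-2.25 ± 0.18 and -2.20 ± 0.18), NT5E (from 10.52 ± 0.26 to 8.52 ± 0.12 in spheres, and -3.89 ± 0.15), WNK4, a kinase (-1.90 ± 0.32 and -1.88 ± 0.32), and CA2, a carbonic anhydrase (-2.36 ± 0.13 and -1.86 ± 0.13). Across genes, though, the changes did not go together, with Pearson r = -0.02 and Spearman rho = -0.004 over 19775 genes.

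Of 1521 genes past the threshold in both comparisons, which share no arrays but share the estimate of each gene's spread, 747 moved the same way and 774 in opposite ways (49.1% the same). Overlaps were larger than those of independent lists in all 4 combinations of directions, but much of that excess was gone once lists were matched in mean level as well as spread, while matching in spread alone left most of it. Higher in both were 352 genes against 218 for independent lists and 281 for lists matched in spread and mean level (Cochran-Mantel-Haenszel adjusted p = 2.9e-06). Lower in both were 395 against 275 and 360 (adjusted p = 0.032). Lower in spheres and higher in the arrays labelled Snail were 535 against 334 and 473 (adjusted p = 0.00057), and the reverse 239 against 180 and 218 (adjusted p = 0.10). These tests count genes as independent, which they are not, so their p-values may be far too small and only describe the overlaps. The count moving the same way was 299 without vector array 1, 341 without vector array 2, 281 without Snail array 1 and 336 without Snail array 2.

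**Figure D3:**
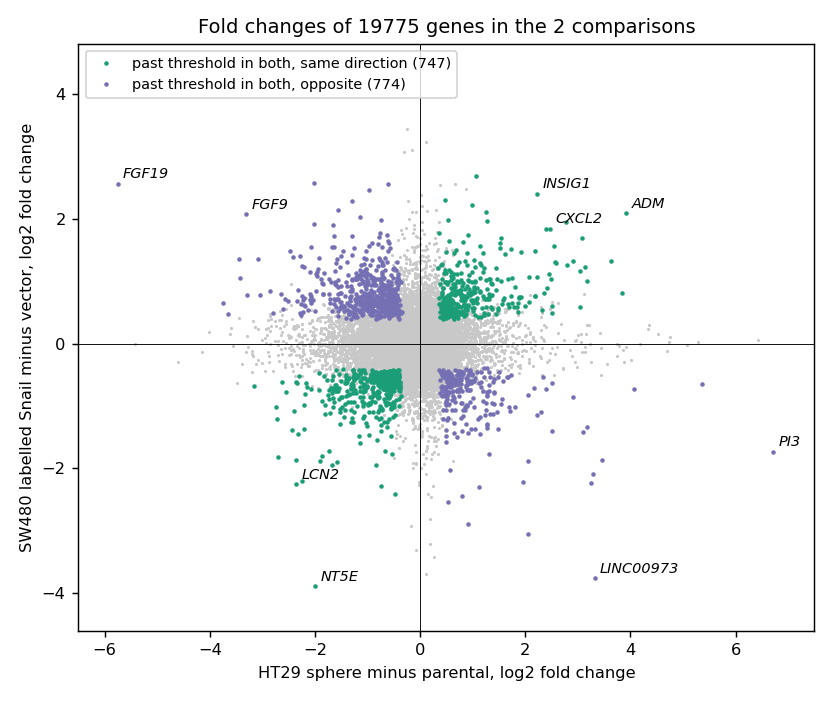
Log2 fold change of each of 19775 genes in HT29 spheres minus parental cells (horizontal) and in SW480 arrays labelled Snail minus vector (vertical). Green points passed the threshold in both with the same direction (747 genes) and purple points with opposite directions (774 genes).

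The difference between the changes, which also holds the difference between the cell lines, passed for 5446 genes. FGF19 stood furthest apart downward: it fell in spheres and rose by 2.56 ± 0.15 in the arrays labelled Snail, a difference of -8.32 ± 0.21 (adjusted p = 3.9e-08). GABRP (-5.40 ± 0.37), FGF9, another growth factor of the FGF family (-5.38 ± 0.21), and LOXL1, a matrix cross-linking enzyme (-4.79 ± 0.24), followed. Upward, the differences were 8.45 ± 0.34 for PI3, 7.07 ± 0.56 for LINC00973, 6.37 ± 0.24 for SPRR1B and 6.01 ± 0.19 for HSPA6. SNAI1 itself rose more in spheres, by 1.06 ± 0.21 (adjusted p = 0.0036). Among the lists, 10 of 21 differed by camera, the cell cycle list downward (adjusted p = 1.4e-16; adjusted p = 0.27 with an estimated correlation) and hypoxia and glycolysis (adjusted p = 1.4e-09; adjusted p = 0.13 with an estimated correlation) leading the 9 upward; 0 differed with an estimated correlation. The epithelial junction list did not pass for the difference (adjusted p = 0.74).

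Other probe sets of a named gene did not always follow the one used. In spheres they differed by more than 1 log2 from it for PI3 (5.37), HSPA6 (3.49), CEACAM7 (3.61), CEACAM5 (0.09), RARRES1 (-2.79), MYB (-0.28), OCLN (2.84), ALCAM (0.08), AXIN2 (1.02), JAG1 (0.09 and 0.32), TNFAIP2 (-0.55), ALDH1A3 (0.06), P4HA1 (0.01), TOP2A (-0.92), TYMS (-0.47), ETV5 (-1.30 and -0.19), LUM, CD44, LGR5, INSIG1 (3.63), CXCL2 (0.26 and 0.35), GDA (-0.83) and NT5E (-0.93 and -0.61). In the arrays labelled Snail this held for APOBEC3G, NT5E (-2.66 and -0.94), PDE8B (-0.13), TCF3 (0.39 and 0.46), CDS1 (-0.18), SPARC (-1.80), TNC (-0.79 and -0.39), CD24 (-1.04), ME1 (0.47), SLC7A11 (0.65), ANKRD37 (-0.29), SREBF1 (0.09), EGR1 (1.07), CD44, CXCL2 (-0.20 and 0.07), GDA (-0.13) and WNK4 (-0.54).

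**Figure D4:**
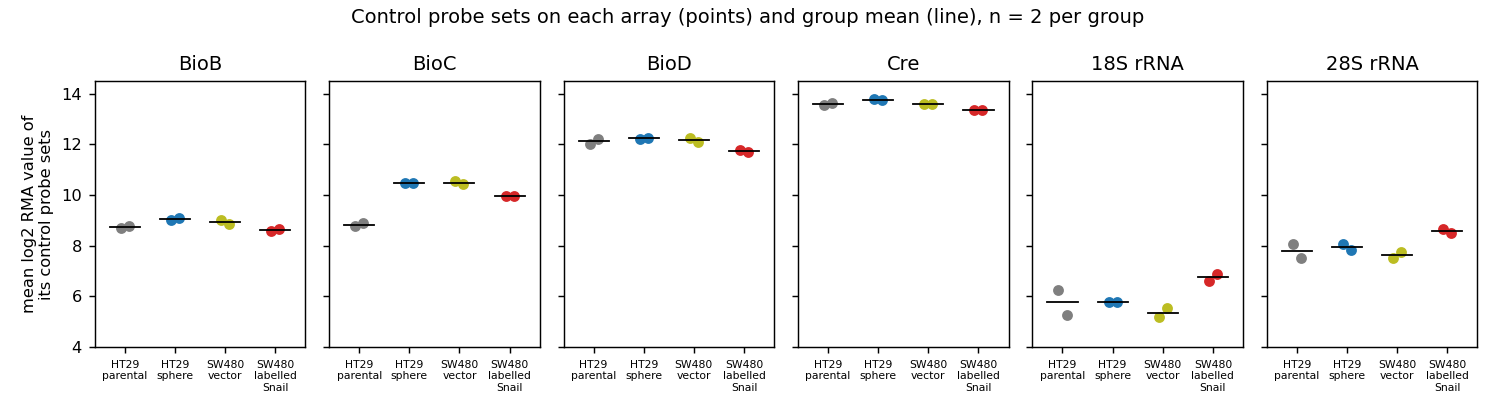
Mean log2 RMA value of the control probe sets of 4 spike-ins and of 18S and 28S ribosomal RNA on each array (points) with the group mean (lines). BioC is lowest on the HT29 parental arrays (8.82), and 18S is highest on the SW480 arrays labelled Snail (6.75).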

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

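Chosen only after the results were seen were the tests of exchanged or wrong labels, of the SNAI1 probe set and of repression in the Snail comparison, those of scaling and hybridisation batch for the cell cycle genes, and that of S phase for the histone genes. The demand that the ribosome list clear the gap between the spheres against each parental array was added then too, as a median above 0 alone had not shown which parental array it came from.

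Control probe sets lie outside the gene comparisons, and 3 of them stood above the control group by at least 0.5 log2 without overlap. BioC was 1.64 log2 higher on sphere than on parental arrays. In the arrays labelled Snail, 18S ribosomal RNA was 1.40 and 28S 0.94 log2 higher than in vector cells. The spike-ins read lower there without overlap (BioC -0.52, BioD -0.44, BioB -0.33 and Cre -0.25 log2), so a hybridisation difference was not separated from the SW480 groups either. Outside the gene table, limma on all probe sets called 214 of 1801 probe sets naming several genes higher and 274 lower in spheres, and 711 of 11721 unnamed ones higher and 655 lower. In the arrays labelled Snail, it called 139 higher and 134 lower, and 315 higher and 466 lower. In percent, 27.1 of the several-gene and 11.7 of the unnamed probe sets passed in spheres, against 26.3 of those naming 1 gene, and 15.2 and 6.66 against 13.3 in the arrays labelled Snail.

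SNAI1 was not higher in the arrays labelled Snail, while 15 of 34 epithelial junction genes were higher and 2 lower. As a list they passed camera at its preset correlation (adjusted p = 2.9e-05) but not with an estimated one (adjusted p = 0.33). The tables argue against a mix-up of single arrays, since each SW480 array correlated better with its partner than with either array of the other group, by at least 0.0145. The SNAI1 probe set was not without response, as its value rose by 1.07 log2 in spheres. No other probe set read SNAI1, so that this rise came from its transcript was not checked. The epithelial median, 0.50 log2 higher with the labels as they stand, is part of the pattern itself and so cannot test repression by the construct. Also open are an exchange of both groups' labels as a whole, since SNAI1 differed by 0.0034 ± 0.15 log2, and a construct outside the reach of the probe set, which was not tested. No technical explanation may therefore be ranked above a true change in the stable line, such as a drift of SW480 cells during selection, also untested.

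All 30 cell cycle genes were lower in HT29 spheres. Scaling by 1 factor per array is argued against by the hypoxia and glycolysis list, whose median rose by 1.44 log2 on the same arrays, while distortion with level was not tested, and RNA quality by 3' to 5' ratios of ACTB and GAPDH that differed by at most 0.21 log2. Slower growth may contribute, and a ribosome biogenesis list was to fall with it. Its median rose by 0.33 log2, but by only 0.003 against parental array 1 alone, less than the gap of 0.11 between the spheres, so it decides nothing. Medium and sphere form cannot be told apart, as 0 sphere arrays had serum. Nor can the culture and a possible hybridisation batch of the parental arrays, which the labels do not name. BioC was 1.64 log2 lower on those arrays, while BioB, BioD and Cre differed by 0.32 log2 or less.

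Histone genes stood among the largest rises in the arrays labelled Snail. Members of a replication histone list not seen before it was written rose as a group, at a median of 0.50 log2 with 9 of 21 past the threshold and 0 lower. More cells in S phase stays open, since the cell cycle list went both ways around a median change of -0.0227 log2, with quartiles of -0.25 and 0.31. Histone messages mostly lack a poly(A) tail, as does ribosomal RNA, which was also higher, so a larger share of such RNA in the labelled material is a candidate explanation. It stays open too, though 18S and 28S were higher as it needs. Of the snoRNA, scaRNA and snRNA genes sought as a test, only 13 snoRNA genes were measured. They went both ways around a median change of 0.0449 log2, and 0 of them passed. Whether their probe sets read the snoRNAs or longer transcripts that hold them was not checked, so they decide nothing.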

How the results depend on the processing

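The counts of list members under each alternative and the overlaps within bins or with each line alone were added after the data were seen; all other alternatives were planned. Testing every probe set raised the counts by construction, to 12665 in spheres, 6520 in the arrays labelled Snail, 11058 for the difference and 1264 moving the same way in both. Within 20 bins of the spread alone, overlaps still exceeded the lists' own rates, 1.28 to 1.57 times, and within bins of spread and level 1.10 to 1.25 times. With each line fitted alone, they were 1.42 to 1.67 times those of independent lists. Requiring a 2-fold change lowered the gene counts to 2024 in spheres, 656 in the arrays labelled Snail, 2832 for the difference and 83 moving the same way in both. The correlation across genes was 0.0055 with the mean of each gene's probe sets; the cause was not tested. Camera with an estimated correlation called 0 lists in spheres and 0 in the arrays labelled Snail, where fry called 15 and 9. Correlation among members does not account for every lost call. The estimate was below the preset 0.01 for NF-kB genes in spheres (-0.0087), yet camera adjusted p went from 1.6e-05 to 0.082. It was -0.0471 for Wnt targets in the arrays labelled Snail, where camera adjusted p went from 0.016 to 0.33. Other lists had estimates above the preset, such as cell cycle genes (0.72). With an estimated correlation limma's camera also uses the 4 residual degrees of freedom, and at a preset correlation a far larger number set by the genes. That 0 lists passed with an estimate thus partly reflects the few arrays. How much of each rise came from this was not tested. Leaving out 1 array gave 4251 to 5885 genes in spheres, 1447 to 4087 in the arrays labelled Snail, 3931 to 5785 for the difference and 281 to 916 moving the same way in both. In those fits the correlation ran from -0.047 (without Snail array 1) to 0.0102 (without Snail array 2), and 9 to 11 lists passed in spheres and 6 to 8 in the arrays labelled Snail. A group left with 1 array is assumed there to vary like the other groups. With the mean of each gene's probe sets the sphere changes of PECAM1 (-0.0948) and TCF3 (0.0744) turned direction, because their probe sets disagree. Quantile normalisation or centring moved the share of higher calls by under 10 percentage points and the median of all genes by under 0.1 log2.

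With the replicate number as a block, 6030 genes passed in spheres, 3105 in the arrays labelled Snail, 5265 for the difference and 676 moving the same way in both, the correlation was -0.0192, and 11 and 7 lists passed. Same-numbered arrays did not deviate together (r = 0.03 in HT29 and -0.03 in SW480), so the numbers do not pair them. Of 17 list calls, 12 held in each of 16 alternatives of arrays, scaling and probe sets, and the exceptions were goblet and metallothionein genes in spheres and Wnt, hypoxia and fatty acid genes in the arrays labelled Snail. Of 128 named values past the threshold, 17 lost the call in some alternative, 16 of them on leaving out an array. These were PECAM1 and TCF3 in spheres, and in the arrays labelled Snail 14 genes (adjusted p 0.051 to 0.28): ABCC5, CDH1, CXCL8, DEFA5, HSPA6, MAP2, MCM6, NOTCH2, PECAM1, PRRX1, RRM2, SCD, TCF3 and VIM. SREBF2 lost its call with the mean of its probe sets (0.35 log2, adjusted p = 0.060). CD44 gained a call in spheres with an intensity trend (adjusted p = 0.040) or without parental array 1 (-0.65 log2, adjusted p = 0.011), and in the arrays labelled Snail LIN28A did with array weights (adjusted p = 0.037). Member counts moved more than 1.5-fold on leaving out an array; those of at least 3 before or after are given here or in the report. In spheres, rises went from 6 to 3 (mesenchymal, without sphere array 1), 4 to 2 (drug efflux and fatty acid, without sphere array 2), 4 to 2 (metallothioneins, without parental array 1 or sphere array 2), 5 to 8 (immediate response, without parental array 1) and 3 to 5 or 1 (other cell types, without parental array 1 or sphere array 1). Falls went from 6 to 2 (immediate response, without sphere array 1) and 4 to 2 (epithelial, without either sphere array), while all 30 cell cycle genes fell without any 1 array. In the arrays labelled Snail, without either parental array, NF-kB falls went from 3 to 6, amino acid rises from 2 to 6, cell cycle falls from 2 to 5 and fatty acid rises from 2 to 4. NF-kB rises went from 5 to 3 and drug efflux rises from 3 to 1 without vector array 1 or Snail array 2, interferon rises from 5 to 3 without either sphere array, and immediate response falls from 3 to 1 without either sphere or vector array and to 0 without Snail array 2. Signal over background was not measured, which limits statements on dim genes.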

Other observations

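The test of the squamous genes was written before its result was seen, on members not seen before, after SPRR1B, PI3, SLPI, SPRR3 and LCN2 had been noticed among the large changes; the comparison of the lines was chosen after the data were seen.

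Genes of the squamous cornified envelope and its secreted inhibitors moved in HT29 spheres. Of 33 measured members 20 rose and 3 fell, at a median of 0.53 log2. The rises included SPRR3 (4.70), SLPI, a leukocyte protease inhibitor (3.83), SERPINB3 (3.22), SPRR1A (3.14), KRT16 (1.87) and IVL, involucrin (0.76), while LCN2 (-2.35), KRT13 (-0.86) and KLK6 (-0.65) fell. Among the 28 members not seen before the list was written, 16 rose and 2 fell, with a median of 0.48 log2, above those of all 10000 random lists of that size. That rank hardly sets the list apart. In spheres ribosome biogenesis genes stood at percentile 100 of random lists of their size and epithelial junction genes at 99.99. Replication histones stood at 99.89, snoRNA genes at 99.31, and cell cycle genes at 0. Random lists ignore correlation among related genes, so the rank is no measure of significance. A group rise in spheres is a hypothesis that these values allow. A possible hybridisation batch of the parental arrays was not separated from it, with BioC 1.64 log2 apart but the other spike-ins 0.32 or less. In the arrays labelled Snail the same 28 genes had a median of -0.03, with 2 rises and 4 falls.

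Replication histones changed in spheres as well. Of 23 measured genes 9 rose, 1 fell (H3C2, -0.69) and the median was 0.29 log2, with H2AC8 at 3.12 and H2BC21 at 3.07, while every cell cycle gene fell. The snoRNA genes, whose own products have no poly(A) tail either, had a median of 0.31 log2 in spheres, with 2 of 13 higher and 0 lower. What their probe sets read was not checked. Ribosomal RNA differed by 0.01 (18S) and 0.13 (28S). The parental arrays lay apart on both (6.27 and 5.28 for 18S, 8.08 and 7.53 for 28S). These mean differences therefore do not show that ribosomal RNA was unchanged. In the arrays labelled Snail 11 rose and 0 fell, at a median of 0.68 log2, led by H2AC6 (2.47) and H2BC12 (2.21). Ribosome biogenesis genes rose in 13 of 35 cases in spheres and fell in 3, among them NOP16 (1.09) upward and FBL, fibrillarin (-0.74), downward. Their median change was 0.003 against parental array 1 alone and 0.585 against parental array 2 alone, so a rise of the list rests on 1 parental array.

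The control groups of the lines differed more than either comparison. Between SW480 vector and HT29 parental cells limma called 9116 genes, 4478 higher and 4638 lower in SW480. VIM was 6.81 ± 0.14 log2 higher in SW480 (adjusted p = 4.1e-10), SPARC 4.26 ± 0.13, SNAI2 2.55 ± 0.28 and ZEB1 1.63 ± 0.15, while PROM1 (-6.73 ± 0.17), CDH1 (-3.38 ± 0.17) and CEACAM5 (-2.72 ± 0.18) were lower. SNAI1 differed by 0.34 ± 0.15 (adjusted p = 0.084). Of 34 epithelial junction genes 29 were lower and 1 higher in SW480 (camera adjusted p = 1.1e-12; adjusted p = 0.087 with an estimated correlation), and 6 of 7 metallothioneins were higher, at a median of 3.36 log2 (camera adjusted p = 2.2e-05; adjusted p = 0.23 with an estimated correlation). Vector, medium composition and line were not separated in this contrast, nor was hybridisation, with BioC at 8.82 on the parental and 10.49 on the vector arrays.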
